A study of Mus musculus with 8 samples.

How the data were processed

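The data describe immune cells of the mouse submandibular gland, a major salivary gland, and of the lymph nodes that drain it. Cells positive for CD45, a surface protein of leukocytes, were sorted from 4 SS and 4 control mice of about 12 weeks. The labels do not spell out SS. They list 8 samples, of which 4 are gene expression libraries and 4 are T cell receptor libraries, with 1 sample for each combination of genotype, tissue and kind of library. No group therefore has a replicate. The expression files came as 4 libraries named C1, C2, C3 and C4; the receptor libraries were not analysed here.

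No label, file header or barcode tied C1 to C4 to a genotype or a tissue. No library was assigned from its content, no SS against control or gland against lymph node comparison was made, and each library's values are given side by side with no test. Per the labels' protocols, glands were digested with collagenase at a raised temperature and lymph nodes were only triturated, a difference in handling that can change genes which respond within minutes. Per the labels' protocols the single-cell libraries also followed the BD Rhapsody whole-transcriptome workflow, while the design text names 10x; the barcodes in the files have 16 bases.

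The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, and per the file headers they were written by Cell Ranger 4. Per the submitters' processing notes, Cell Ranger 6.1.2, STAR 2.7.10a and the mm10 genome build were used; why the version differs from the header is not given in the sources used here. Each matrix lists the same 32285 genes. The matrices were not restricted to cells: 407145 barcodes of C1, 389877 of C2, 468934 of C3 and 348345 of C4 held at least 1 UMI, with total counts of 48439860, 44798843, 77819179 and 37902916 UMIs.

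Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept. Doublets, barcodes that hold more than 1 cell, were called per library with Scrublet in scanpy 1.11.5 and removed. It called 166 barcodes (2.96%) in C1, 0 in C2, 2 (0.0234%) in C3 and 116 (1.95%) in C4, so it did not work in C2 and C3, and doublets remain there. The kept barcodes numbered 5450 in C1, 5067 in C2, 8530 in C3 and 5841 in C4, with median depths of 6130, 4939, 8076 and 5158 UMIs. Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable genes were taken, leaving out receptor V, D and J genes. Clustering of the 4 libraries together used 30 principal components, 15 neighbours and Leiden (leidenalg 0.10.2) at resolution 1 with seed 0 and no batch integration. Other tools were Python 3.11.15, scipy 1.17.1, scikit-learn 1.9.0, numpy 2.4.6 and matplotlib 3.10.9.

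Clusters were named from marker lists chosen before the data were examined, so a class is written T-like, B-like and so on. The step that turns markers into a name was set after clusters had been seen and had 2 versions. In the version used, a class needed at least 3 markers, each found in at least 10% of the cluster's barcodes, and the class with the highest scaled mean marker level of at least 0.5 gave the name. A cluster stayed unnamed where its 10 leading genes by fold held more markers of another class than of its own, or where its depth was under 33.3% of its libraries' medians and none of those genes was its marker. The first version had no marker minimum before the best class was taken and left ties unnamed; its values are among the alternatives. Of 36 clusters, 13 were T-like and 4 stayed unnamed. A cluster mostly of 1 library can be that library rather than a cell type.

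UMIs were summed over the barcodes of a class in a library and given as CPM, the UMIs of a gene per 1000000 UMIs of that class. Shares carry exact Clopper-Pearson 95% binomial intervals and levels exact Poisson 95% intervals; both cover counting error only, not the spread between mice. A count of 0 allows up to 3 counts. Shares of barcodes with a UMI were recomputed after thinning each T-like barcode to 3465 UMIs, the percentile 10 depth of that class. The genes named were chosen by a rule written before the data were examined: in each of 13 fixed lists, up to 4 members with the highest median CPM over libraries, plus the member of largest highest-over-lowest ratio with at least 50 UMIs in its highest library. For T-like and B-like barcodes the rule also took the 10 genes of largest ratio with at least 100 UMIs, if each library held 200 barcodes of the class, leaving out salivary marker, erythroid and receptor genes. The B-like class did not reach that number. A count of 0 in the lowest library was set to 3 counts for these ratios. Interferon response values in macrophage-like barcodes and all genes said to be singled out were added after values were seen. Values of some genes that the rule names are not reported here. Gene positions come from the RefSeq table for the mm10 assembly, the assembly named in the processing notes, in which 83 of 85 symbols matched. Hspa1a and Hspa1b, Iglc2 and Iglc3, the Dcpp genes, the Scgb2b genes and some Trbv genes are near-identical copies whose counts are uncertain one by one.

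The clustering, naming and summing steps were tested on simulated data. All 1000 simulated barcodes of each of the T-like, B-like, NK-like and macrophage-like profiles were given their class, but these profiles were built from barcodes picked by the same markers, so the test is an easy one. For gene levels over 32285 genes, 50 genes changed 4-fold were recovered at a median of 3.83-fold, 50 changed 2-fold at 1.89-fold, 50 changed 0.5-fold at 0.479-fold and 50 changed 0.25-fold at 0.238-fold. Of 2385 unchanged genes, 6.16% had intervals that lay apart, at a median of 0.950-fold, because the changed genes shift the total that CPM divides by. Rescaling by the known total, tried after that result was seen, brought this to 0.545%. The simulated counts had Poisson spread only, so that low value was favoured in advance. The test does not show how the intervals hold where the UMIs of a gene lie in few barcodes. The true total is not known for C1 to C4 and their values are not rescaled, so small differences between CPM values can come from other genes.

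Alternatives were a minimum of 1000 UMIs, at most 5% mitochondrial UMIs, doublet calls kept, resolutions 0.5 and 2, each library clustered alone, a class per barcode from its own marker UMIs and, for near-empty barcodes, a bound of 20 instead of 50 UMIs. Alternatives chosen after seeing the data were removal of the top 5% of doublet scores, the first naming rule, a CPM total without ribosomal RNA overlapping, mitochondrial and salivary genes, near-empty barcodes of at least 50 and under 200 UMIs, and a salivary list with Mucl2, Car6, Wfdc18 and Scgb genes added. A further restriction on the T-like ratio genes, the B cell maturation and activation list sums without Nr4a1, every list sum under each alternative or without genes that another list of the class holds, Igha in B-like barcodes, the B-like class without the cluster of highest doublet score, and early response in every pair of libraries rather than pairs with at least 40 barcodes each were also chosen after values were seen.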

Results

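Single-cell expression was measured in leukocytes sorted from the submandibular gland and its draining lymph nodes of SS and control mice, with 4 libraries for the 4 combinations of genotype and tissue. The series concerns the make-up of the immune cells in the gland of SS mice. The libraries C1 to C4 could not be tied to a genotype or tissue, so the values below describe each library and carry no comparison between SS and control or between tissues. Total depth was 48439860 UMIs in C1, 44798843 in C2, 77819179 in C3 and 37902916 in C4. There were no replicates; intervals in parentheses are 95% intervals for counting error.

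T-like barcodes, marked by the T cell receptor complex genes Cd3d, Cd3e and Trac, made up 10.9% (10.1 to 11.8%) in C1, 64.6% (63.3 to 65.9%) in C2, 88.0% (87.3 to 88.6%) in C3 and 64.6% (63.3 to 65.8%) in C4. With a class per barcode the T-like share was 67.9% in C2 and 67.1% in C3, so that C3 no longer lay above C2, and under the first naming rule it was 48.1% in C4. Macrophage-like barcodes, marked by complement genes such as C1qa and by Csf1r, made up 44.5% (43.2 to 45.8%) in C1, 9.06% (8.28 to 9.88%) in C2, 0.281% (0.180 to 0.418%) in C3 and 0.0685% (0.0187 to 0.175%) in C4. NK-like barcodes, marked by the receptor gene Ncr1, made up 25.7% (24.5 to 26.8%) in C1, 7.42% (6.71 to 8.18%) in C2, 0.211% (0.125 to 0.333%) in C3 and 0.565% (0.389 to 0.793%) in C4. With a class per barcode they were 14.6% in C2 and 1.11% in C3, above the 0.599% in C4. The cytotoxic granule gene Nkg7 is among the NK markers summed there, and T-like barcodes carried it at 4072 CPM in C2 and 1367 in C3. T cells can therefore be counted as NK-like with that choice. The myeloid-like share, which holds the macrophage-like one, was then 22.8% in C3, against 2.10% from clusters, and 3.18% in C4, against 1.20%. That choice counts Ly6c2 as a myeloid marker, and T-like cluster 0, mostly of C3, carries Ly6c2 at 2645 CPM. T cells of C3 can therefore be counted as myeloid-like there. B-like barcodes, marked by Cd79a and Ms4a1, made up 1.14% (0.873 to 1.46%) in C1, 0.197% (0.0947 to 0.363%) in C2, 8.63% (8.04 to 9.24%) in C3 and 33.1% (31.9 to 34.3%) in C4. C2 had no B-like barcodes with each library clustered alone. Plasma-like barcodes, the antibody-secreting class, were 43 in C1, 22 in C2, 36 in C3 and 0 in C4, where 0 of 5841 allows up to 0.0514%. Innate lymphoid-like barcodes were 43 in C1 and 7 in C2, with 0 in C3 and C4, which allows up to 0.0352% and 0.0514%. Monocyte-like, dendritic-like and plasmacytoid-like barcodes were each under 2% in every library. Epithelium-like barcodes were 0.312% in C1 and 2.17% in C2, and endothelium-like barcodes 1.03% and 0.336%, despite the CD45 sort. Unnamed cluster 17, led by Klk1, held 213 barcodes in C1 and 82 in C2, and unnamed cluster 14, led by Smgc, held 427 in C1. Both had salivary genes among their leading genes, although macrophage markers scored highest. Neither is counted as epithelium-like, so that share and its order in C1 and C2 depend on what they are. Unnamed clusters held 12.7% in C1, 12.7% in C2, 0.680% in C3 and 0.565% in C4, so shares depend on what those clusters are. The sort and the minimum depth also set these shares.

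**Figure D1:**
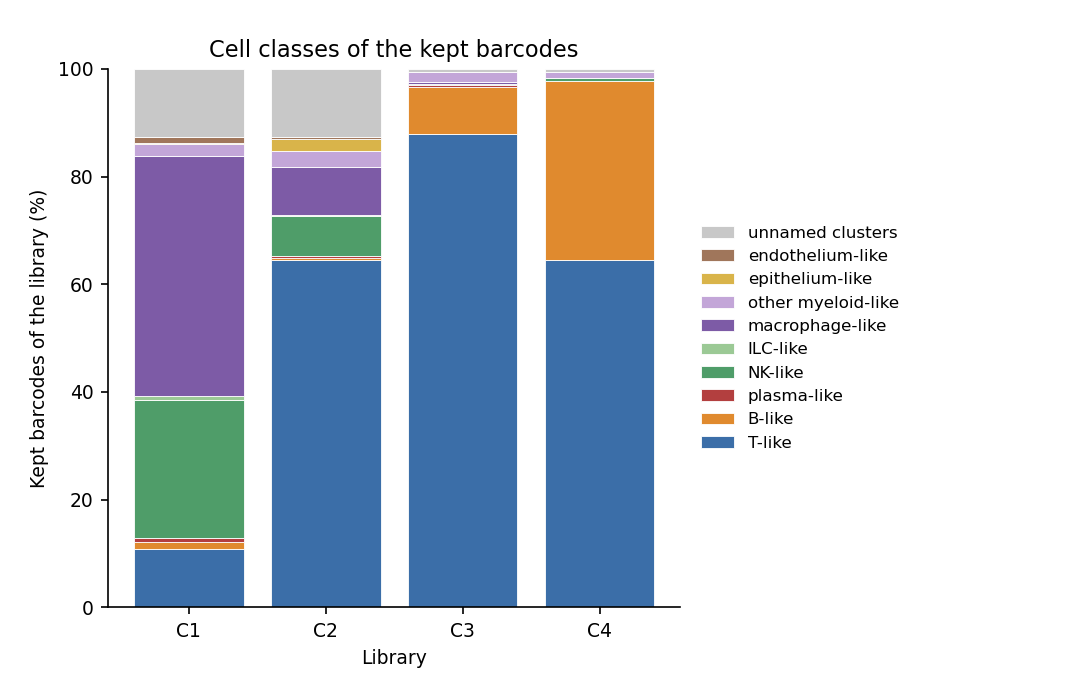
Share of kept barcodes (y axis, percent) in each cell class for the libraries C1 to C4 (x axis); stacked colours are classes named from markers, and grey is unnamed clusters. T-like barcodes are 88.0% of C3 and macrophage-like barcodes 44.5% of C1.

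Clusters 1 and 9 held most T-like barcodes of C1 and C2 in different proportions, and other clusters held most of those of C3 and C4. Cluster 9, led by the cytokine gene Il17a and by Cd40lg and Icos, held 50.7% (46.6 to 54.8%) of T-like barcodes in C1 and 9.56% (8.58 to 10.6%) in C2. An Il17a UMI was found in 11.9% of all T-like barcodes in C1 and 0.855% in C2. Most barcodes of cluster 9 in these libraries therefore had none. Cluster 1, led by the granzyme gene Gzmk and the inhibitory receptor genes Pdcd1 and Lag3, held 36.1% (32.2 to 40.1%) in C1 and 67.1% (65.4 to 68.7%) in C2, and cluster 11, led by Lag3 and Pdcd1, held 13.9% (12.8 to 15.2%) in C2. Cluster 0, led by Gzmm, Ly6c2 and Il7r, held 59.5% (58.4 to 60.6%) in C3 and 6.55% (5.78 to 7.39%) in C4. Clusters 3 and 7, which both have the naive T cell gene Lef1 among their leading genes, held 48.3% (46.7 to 50%) and 25.5% (24.2 to 27.0%) in C4. Cluster 12, led by Foxp3, the lineage factor gene of regulatory T cells, held 2.68% (1.54 to 4.32%) in C1, 2.44% (1.94 to 3.03%) in C2, 1.15% (0.918 to 1.41%) in C3 and 7.21% (6.41 to 8.09%) in C4. Because most clusters lie in 1 or 2 libraries, their leading genes identify them and are not results.

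**Figure D2:**
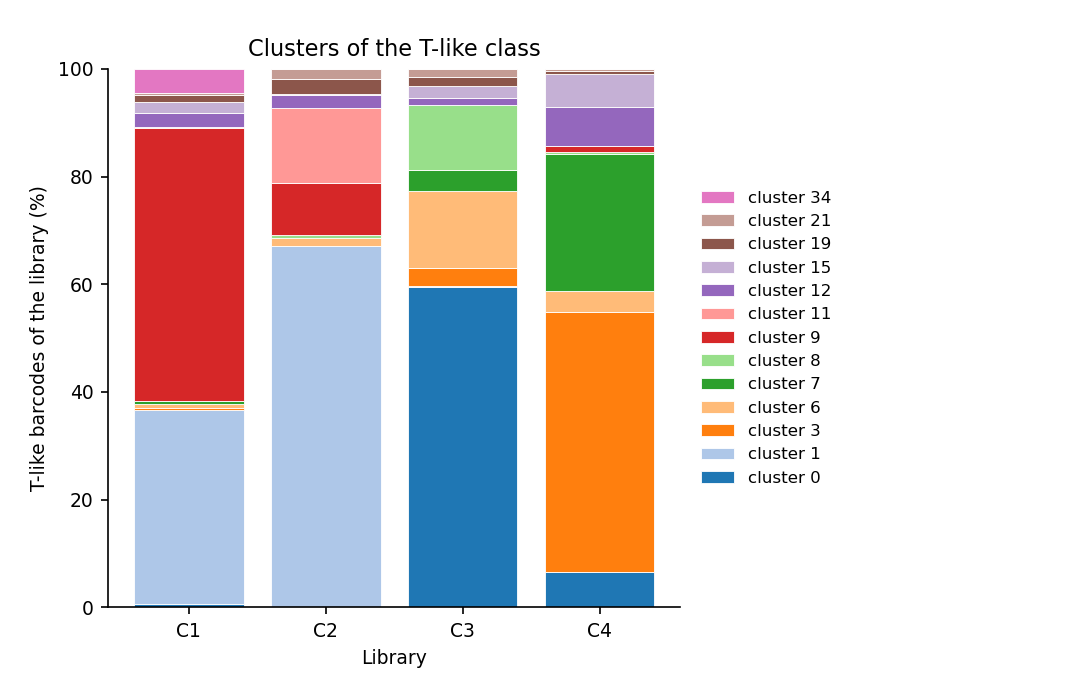
Share of T-like barcodes (y axis, percent) in each of 13 T-like clusters for the libraries C1 to C4 (x axis); colours are clusters. Cluster 0 fills 59.5% of the T-like class in C3, cluster 1 67.1% in C2, cluster 9 50.7% in C1 and cluster 3 48.3% in C4.

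Barcodes with Cd8a or Cd8b1 UMIs and no Cd4 UMI, the co-receptor genes that mark the CD8 and CD4 lineages, were 32.4% (28.6 to 36.3%) in C1, 67.0% (65.4 to 68.6%) in C2, 72.3% (71.3 to 73.3%) in C3 and 29.3% (27.8 to 30.8%) in C4 of T-like barcodes. Barcodes with Cd4 and no Cd8 UMI were 45.0% (40.9 to 49.1%) in C1, 22.3% (20.9 to 23.8%) in C2, 17.2% (16.3 to 18.1%) in C3 and 43.4% (41.8 to 45.0%) in C4. Among B-like barcodes, which should lack both, the shares with Cd8 only were 6.66% in C3 and 0.879% in C4, and with Cd4 only 2.31% and 0.569%. In C3, 69 of these were cluster 23, with a mean doublet score of 0.158, of which 46.4% had Cd8 only; without it, a split chosen after values were seen, the share in C3 was 2.55% (1.49 to 4.05%). Median depths were 8257.0 UMIs for T-like and 5326.5 for B-like barcodes in C3, and 6087.0 and 3895.5 in C4. In macrophage-like barcodes of C1 and C2, Cd8 only was 0.413% and 7.19%. At an equal depth of 3465 UMIs, Cd8b1 was found in 32.5% in C1 (32.4% before thinning), 68.6% in C2 (68.0% before thinning), 75.0% in C3 (74.2% before thinning) and 32.8% in C4 (35.1% before thinning), leaving out 67, 557, 607 and 280 shallower barcodes.

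The T effector list, 19 cytokine and cytotoxicity genes, summed in T-like barcodes to 9446 CPM in C1 (9342 to 9551), 30753 in C2 (30674 to 30832), 8991 in C3 (8968 to 9014) and 910 in C4 (898 to 922). Its leading member Ccl5, a chemokine of effector T cells, was at 4283 CPM in C1 (4213 to 4354), 19898 in C2 (19835 to 19962), 6985 in C3 (6964 to 7005) and 492 in C4 (483 to 501). Nkg7, a gene of cytotoxic granules, was at 1230 CPM in C1, 4072 in C2, 1367 in C3 and 297 in C4. Ccl4, another chemokine, was at 935 CPM in C1, 3068 in C2, 160 in C3 and 12.0 in C4. Ifng, which encodes interferon gamma, was at 423 CPM in C1 (401 to 446), 276 in C2 (268 to 283), 32.1 in C3 (30.7 to 33.5) and 5.42 in C4 (4.55 to 6.42). Ccl3 had the largest ratio between libraries in this list, at 109 CPM in C1, 1153 in C2, 28.0 in C3 and 1.61 in C4. These levels stood beside different clusters: mostly 1 and 11 in C2, 0 in C3, and 3 and 7 in C4. With each library clustered alone C4 had 29.3 CPM of Ccl5, 2.74 CPM of Ccl4, 1.42 CPM of Ifng, 0.615 CPM of Ccl3 and 310 CPM for the list, and under the first naming rule it had 192 CPM of Nkg7. With a minimum of 1000 UMIs Ccl3 in C1 was 301 CPM, and without the top 5% of doublet scores Ccl3 in C2 was 511 CPM. Ccl5 lies at chromosome 11, 83525778 to 83530518, Ccl3 at chromosome 11, 83647843 to 83649378 and Ccl4 at chromosome 11, 83648624 to 83664683. The annotated spans of Ccl3 and Ccl4 overlap. Their strands were not compared, and whether their counts share reads was not tested.

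The list of activation and inhibitory receptors, 13 genes, summed to 3989 CPM in C1 (3921 to 4057), 4024 in C2 (3996 to 4053), 959 in C3 (951 to 966) and 814 in C4 (803 to 826). Nr4a1, an early target gene, was a member, and without it, a sum added after values were seen, the list was at 3035 (2976 to 3095) CPM in C1, 3758 (3731 to 3786) in C2, 947 (939 to 954) in C3 and 773 (762 to 784) in C4. Without Cd69, Pdcd1 and Icos, which other lists also hold, it was 2494 CPM in C1, 2778 in C2, 517 in C3 and 465 in C4. Cd69, an early activation marker, was at 868 CPM in C1, 472 in C2, 342 in C3 and 285 in C4. Ctla4, an inhibitory receptor gene, was at 667 CPM in C1, 416 in C2, 77.1 in C3 and 82.8 in C4. The costimulatory receptor gene Icos was at 528 CPM in C1, 242 in C2, 75.1 in C3 and 54.3 in C4. Cd28 was at 266 CPM in C1, 241 in C2, 123 in C3 and 126 in C4. The order of C1 and C2 turned with a class per barcode, at 238 CPM and 252 CPM. Havcr2, which encodes the inhibitory receptor TIM-3, was at 19.9 CPM in C1 (15.4 to 25.3), 159 in C2 (153 to 165), 5.64 in C3 (5.08 to 6.25) and 0.924 in C4 (0.586 to 1.39); without the top 5% of doublet scores its level in C2 was 90.1 CPM.

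Genes of naive and recirculating T cells, 8 in the list, summed to 1692 CPM in C1 (1648 to 1737), 605 in C2 (594 to 616), 2557 in C3 (2544 to 2569) and 3344 in C4 (3321 to 3367). Ccr7, a lymph node homing gene, was at 149 CPM in C1, 18.1 in C2, 174 in C3 and 417 in C4. The transcription factor gene Tcf7 was at 162 CPM in C1, 93.1 in C2, 360 in C3 and 524 in C4. Klf2 was at 715 CPM in C1, 229 in C2, 546 in C3 and 694 in C4. Il7r, the receptor gene for a survival cytokine, was at 408 CPM in C1, 141 in C2, 525 in C3 and 391 in C4. At equal depth, a Ccr7 UMI was found in 10.6% in C1 (11.4% before thinning), 2.98% in C2 (3.70% before thinning), 41.1% in C3 (61.7% before thinning) and 70.1% in C4 (82.4% before thinning) of T-like barcodes.

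The list of tissue residency and homing, with 9 of 10 symbols found, summed to 4745 CPM in C1 (4671 to 4819), 2847 in C2 (2824 to 2872), 975 in C3 (968 to 983) and 839 in C4 (828 to 851). Without Cd69, which the activation list also holds, it was 3877 CPM in C1, 2375 in C2, 633 in C3 and 554 in C4. Rgs1, a regulator of chemokine receptor signalling, was at 2350 CPM in C1, 1415 in C2, 151 in C3 and 150 in C4. Cxcr6, a chemokine receptor gene of resident T cells, was at 666 CPM in C1, 495 in C2, 62.0 in C3 and 30.4 in C4. The integrin gene Itga1 was at 90.8 CPM in C1, 22.6 in C2, 1.57 in C3 and 0.924 in C4. Itgb7 was at 414 CPM in C1, 193 in C2, 219 in C3 and 289 in C4. In the same barcodes the early response list, given further on, was at 9513 CPM in C1 and 1822 in C3. Itga1 was 0.814 CPM in C3 and 0.0473 CPM in C4 with each library clustered alone, and Itgb7 without the top 5% of doublet scores was 224 CPM in C2, above the 219 CPM in C3.

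**Figure D3:**
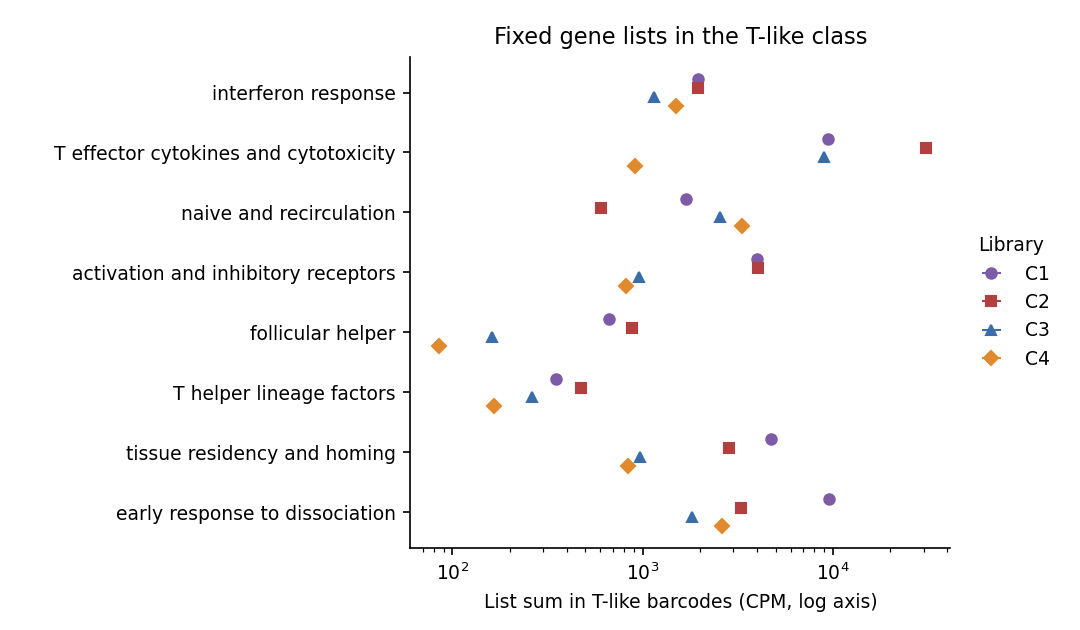
Sum of each fixed gene list in T-like barcodes (x axis, CPM on a log axis) for the libraries C1 to C4; points are library sums and bars their 95% Poisson intervals, mostly narrower than the points. The T effector list ranges from 910 CPM in C4 to 30753 in C2.

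The follicular helper list, 7 genes of the T cells that help B cells, summed in T-like barcodes to 666 CPM in C1 (638 to 694), 880 in C2 (867 to 893), 162 in C3 (159 to 165) and 84.6 in C4 (81.0 to 88.3). Icos and Pdcd1, also in the activation list, made up most of the sum in every library. A sum without these and Il21, which other lists hold, was added after values were seen. It was 28.0 CPM in C1 (22.6 to 34.3), 100 in C2 (95.9 to 105), 56.4 in C3 (54.6 to 58.3) and 20.2 in C4 (18.4 to 22.0), with C1 below C3. Cxcr5, the homing receptor gene of the list, was at 2.41 CPM in C1, 8.10 in C2, 17.5 in C3 and 6.55 in C4; it is outside the rule and was added after values were seen. Pdcd1, which encodes PD-1, was at 98.7 CPM in C1, 532 in C2, 24.6 in C3 and 9.44 in C4. Bcl6, the lineage factor gene of follicular helper cells, was at 16.5 CPM in C1 (12.5 to 21.5), 8.73 in C2 (7.45 to 10.2), 9.10 in C3 (8.38 to 9.86) and 9.84 in C4 (8.65 to 11.2). Tox2 was at 9.02 CPM in C1, 65.7 in C2, 14.7 in C3 and 3.21 in C4. Sostdc1 was at 17.8 CPM in C2, 15.1 in C3 and 0.562 in C4, with 0 UMIs in C1. The list of T helper lineage factors summed to 351 CPM in C1 (331 to 372), 475 in C2 (466 to 485), 262 in C3 (258 to 266) and 165 in C4 (160 to 170). Eomes, a factor of cytotoxic cells, was at 39.1 CPM in C1, 223 in C2, 128 in C3 and 32.8 in C4. Tbx21, a factor of type 1 cells, was at 108 CPM in C1, 67.7 in C2, 56.5 in C3 and 10.4 in C4. Gata3 was at 74.6 CPM in C1, 46.4 in C2, 37.2 in C3 and 34.1 in C4. Ikzf2 was at 76.1 CPM in C1, 120 in C2, 33.8 in C3 and 50 in C4. With each library clustered alone C4 had 0.662 CPM of Tox2, 0.0473 CPM of Sostdc1, 15.5 CPM of Eomes and 2.69 CPM of Tbx21. Eomes with a class per barcode was 21.8 CPM in C1 and 26.8 CPM in C4, so that C1 no longer lay above C4.

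Of 8760 genes that could pass the ratio rule in T-like barcodes, the 10 with the largest ratio were Mucl2, Scgb1b27, Scgb2b27, Car6, Scgb2b26, Mup5, Igfbp4, Wfdc12, Ccl3 and Gm156. Mucl2 was at 5717 CPM in C1, 9603 in C2 and 0.121 in C4, with 0 UMIs in C3. Igfbp4, an insulin-like growth factor binding protein gene at chromosome 11, 99040005 to 99052655, was at 48.7 CPM in C1 (41.5 to 56.8), 0.631 in C2 (0.326 to 1.10), 70.0 in C3 (67.9 to 72.0) and 541 in C4 (532 to 550). Gm156 was at 0.602 CPM in C1 and 29.5 in C2, with 0 UMIs in C3 and C4. A further restriction, chosen after values were seen, left out the 553 genes that C1 or C2 held at a higher level in barcodes of at least 50 and under 200 UMIs than in T-like barcodes. Igfbp4 and Ccl3 were among them, so their levels in C1 or C2 can include free RNA. The 10 genes of largest ratio were then Gm156, Il17a, Tmem273, Adgrg1, Il17f, Cd163l1, Glp1r, Stk32c, Gzmk and Mmp9. Il17a, at chromosome 1, 20730905 to 20734496, was at 1031 CPM in C1 (997 to 1066), 42.6 in C2 (39.8 to 45.7), 1.91 in C3 (1.59 to 2.28) and 2.53 in C4 (1.94 to 3.24). An Il17a UMI was found in 11.9% of T-like barcodes in C1 and 0.855% in C2, so these levels rest on a minority of barcodes. Il17f, a relative of Il17a, was at 68.6 CPM in C1, 9.31 in C2, 0.170 in C3 and 2.29 in C4. Gzmk was at 127 CPM in C1, 760 in C2, 110 in C3 and 2.69 in C4.

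The interferon response list, with 13 of 14 symbols found, summed in T-like barcodes to 1957 CPM in C1 (1910 to 2006), 1951 in C2 (1932 to 1971), 1149 in C3 (1140 to 1157) and 1490 in C4 (1475 to 1505). In B-like barcodes it summed to 1121 CPM in C1 (1013 to 1236), 843 in C3 (820 to 866) and 1117 in C4 (1095 to 1140). In C1 this sum was 862 CPM with a class per barcode, below the 881 CPM in C3, and 937 to 946 CPM, below C4, with a minimum of 1000 UMIs, at most 5% mitochondrial UMIs or each library clustered alone. In macrophage-like barcodes, added to the list's classes after values were seen, it summed to 2099 CPM in C1 (2077 to 2121) and 2716 in C2 (2668 to 2765). In T-like barcodes Isg15 was at 159 CPM in C1, 90.4 in C2, 36.2 in C3 and 57.0 in C4. Ifi27l2a was at 872 CPM in C1, 948 in C2, 521 in C3 and 772 in C4. Bst2 was at 172 CPM in C1, 115 in C2, 121 in C3 and 110 in C4. Zbp1 was at 100 CPM in C1, 116 in C2, 53.9 in C3 and 67.3 in C4. Usp18 in B-like barcodes was at 11.3 CPM in C1, 5.26 in C3 and 16.5 in C4, and Irf7 at 47.9 CPM in C1, 24.4 in C3 and 56.2 in C4. Usp18 in B-like barcodes of C1 was 6.16 CPM with a class per barcode, and Ifi27l2a in T-like barcodes 737 CPM in C1 and 781 CPM in C4, the other order. In macrophage-like barcodes Zbp1 was at 50.3 CPM in C1 and 133 in C2, and Bst2, in the other direction, at 787 CPM in C1 and 571 in C2. Ifi27l2a there was at 535 CPM in C1 and 737 in C2, and Irf7 at 107 CPM in C1 and 146 in C2. Macrophage-like barcodes were mostly cluster 4 in C1 (77.1%) and cluster 13 in C2 (69.7%).

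B-like barcodes of C1, C3 and C4 numbered 62, 736 and 1934; those of C2 numbered 10 and are left out. The list of B cell maturation and activation, with 13 of 14 symbols found, summed to 3829 CPM in C1 (3628 to 4038), 2222 in C3 (2185 to 2259) and 2472 in C4 (2439 to 2505). Ms4a1, which encodes CD20, was at 853 CPM in C1, 1013 in C3 and 945 in C4. Fcer2a, which encodes CD23, was at 282 CPM in C1, 310 in C3 and 573 in C4. Nr4a1, an early target of antigen receptor signalling, was at 1602 CPM in C1 (1473 to 1739), 16.4 in C3 (13.4 to 19.9) and 72.7 in C4 (67.2 to 78.6). Without Nr4a1, a sum added after values were seen, the list was at 2227 (2075 to 2388) CPM in C1, 2206 (2169 to 2243) in C3 and 2399 (2366 to 2432) in C4. The early response list in the same barcodes was at 8531 CPM in C1, 1716 in C3 and 2120 in C4. S1pr3, a marginal zone receptor gene, was at 12.9 CPM in C3 and 4.26 in C4, with 0 UMIs in C1. B-like barcodes of C1 were mostly cluster 32 (75.8%), and those of C3 and C4 mostly cluster 2 (67.3% and 88.2%). Cluster 18 was led by Mef2b and had the germinal centre gene Rgs13 among its leading genes. It held 16.1% (8.02 to 27.7%, 10 barcodes) in C1, 23.1% (20.1 to 26.3%) in C3 and 4.29% (3.43 to 5.29%) in C4.

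The immunoglobulin constant region list summed in B-like barcodes to 9260 CPM in C1 (8946 to 9582), 4924 in C3 (4869 to 4979) and 5372 in C4 (5324 to 5421). Under 4 alternatives the sum in C1 fell: with a minimum of 1000 UMIs, where C1 had 60 B-like barcodes, it was 4127 CPM in C1, 3837 in C3 and 5371 in C4, so that C1 no longer lay above C4. It was 4209 CPM in C1 with at most 5% mitochondrial UMIs, 4238 with each library clustered alone and 4152 with a class per barcode. In plasma-like barcodes it summed to 131655 CPM in C1 (131051 to 132261), 118610 in C2 (117870 to 119353) and 103704 in C3 (103106 to 104306). Igha, the heavy chain gene of IgA, was at 41252 CPM in C1 (40915 to 41592), 34332 in C2 (33935 to 34733) and 11970 in C3 (11767 to 12175) in plasma-like barcodes. Jchain, which joins IgA and IgM, was at 56101 CPM in C1, 54534 in C2 and 25774 in C3. Igkc was at 30775 CPM in C1, 25197 in C2 and 33359 in C3. Iglc2 was at 1880 CPM in C1, 2075 in C2 and 1527 in C3. Ighe was at 4.34 CPM in C1 and 398 in C3, with 0 UMIs in C2. In B-like barcodes Ighm was at 664 CPM in C1, 571 in C3 and 834 in C4. Igkc was at 3075 CPM in C1, 1363 in C3 and 1197 in C4. Iglc2 was at 1047 CPM in C1, 789 in C3 and 1566 in C4, and Iglc3 at 532 CPM in C1, 549 in C3 and 994 in C4. Jchain there was at 1070 CPM in C1, 686 in C3 and 104 in C4, but under those 4 alternatives it was 110 to 114 CPM in C1 and 363 to 367 CPM in C3, and Igkc 1034 to 1111 CPM in C1 and 944 to 972 CPM in C3, both then below C4. Igha there, a gene outside the rule for this class and added after values were seen, was at 2385 CPM in C1, 163 in C3 and 6.79 in C4. In C1, 820 of its 847 UMIs lay in 2 barcodes, and in C3 835 of 1019. Under the 4 alternatives Igha was 87.0 to 123 CPM in C1 and 4.32 to 4.46 CPM in C3, so its values in C1 and C3 come mostly from 2 barcodes each. With a class per barcode plasma-like barcodes had 32866 CPM of Jchain in C1 and 29359 in C2, 24401 CPM of Igha in C1 and 18494 in C2, and 18257 CPM of Igkc in C1 and 13582 in C2. Iglc2 was then at 1101 CPM in C1 and 1118 in C2, both now below C3, Ighe at 2.53 CPM in C1, and the list at 77590 CPM in C1, 63883 in C2 and 85281 in C3, so that C3 lay highest. With a minimum of 1000 UMIs Igkc in plasma-like barcodes was 30642 CPM in C1 and 29663 in C3, the other order.

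The antigen presentation list of MHC class II genes summed in B-like barcodes to 35841 CPM in C1 (35221 to 36470), 32075 in C3 (31935 to 32215) and 40484 in C4 (40350 to 40618). In myeloid-like barcodes it summed to 90334 CPM in C1 (90194 to 90474), 85319 in C2 (85085 to 85554), 45531 in C3 (45228 to 45835) and 31226 in C4 (30816 to 31640). Cd74, the invariant chain gene, was at 48915 CPM in C1, 44896 in C2, 21791 in C3 and 16018 in C4 in myeloid-like barcodes. In B-like barcodes Cd74 was at 20469 CPM in C1, 18364 in C3 and 23321 in C4. In myeloid-like barcodes H2-Aa was at 14351 CPM in C1, 12876 in C2, 8655 in C3 and 5554 in C4. H2-Ab1 was at 13146 CPM in C1, 13266 in C2, 6965 in C3 and 4762 in C4. H2-Eb1 was at 13121 CPM in C1, 12988 in C2, 7076 in C3 and 4203 in C4. Cd40, a costimulatory receptor gene, was at 19.0 CPM in C1, 120 in C2, 160 in C3 and 134 in C4. H2-DMb1 in B-like barcodes was at 149 CPM in C1, 70.2 in C3 and 133 in C4. The myeloid-like class holds macrophage-, monocyte-, dendritic-, plasmacytoid- and neutrophil-like clusters, numbered 2544 barcodes in C1, 609 in C2, 179 in C3 and 70 in C4, and was mostly macrophage-like in C1 and C2. With a class per barcode the list was 4963 CPM in C3 and 11961 CPM in C4, and all 5 genes had lower levels there, with C3 now below C4: Cd74 was 2385 CPM in C3 and 6215 CPM in C4, H2-Aa 929 CPM and 2101 CPM, H2-Ab1 763 CPM and 1806 CPM, and H2-Eb1 756 CPM and 1563 CPM. H2-Ab1 in C4 was 2357 CPM and H2-Eb1 2251 CPM with each library clustered alone. Cd40 with a class per barcode was 17.4 CPM in C1, 16.3 CPM in C3 and 52.5 CPM in C4, so that C3 no longer lay above C1. A class per barcode counts Ly6c2 as a myeloid marker, and T-like cluster 0 carries it at 2645 CPM. The myeloid-like share of C3 was then 22.8%, against 2.10% from clusters. These lower levels in C3 and C4 can therefore come from T cells counted as myeloid-like.

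The list of myeloid cytokines and chemokines, 20 genes, summed in myeloid-like barcodes to 25653 CPM in C1 (25578 to 25727), 12477 in C2 (12387 to 12567), 3202 in C3 (3122 to 3283) and 3239 in C4 (3108 to 3374). The early response list in macrophage-like barcodes was at 33436 CPM in C1 and 11727 in C2, and these barcodes were mostly cluster 4 in C1 (77.1%) and cluster 13 in C2 (69.7%). Il1b, which encodes an inflammatory cytokine, was at 3398 CPM in C1 (3371 to 3425), 1697 in C2 (1664 to 1731), 161 in C3 (144 to 180) and 223 in C4 (190 to 261). Ccl4 was at 11187 CPM in C1, 3697 in C2, 58.3 in C3 and 83.3 in C4. Ccl3 was at 3844 CPM in C1, 998 in C2, 33.1 in C3 and 33.9 in C4. Ccl5 was at 171 CPM in C1, 1320 in C2, 1563 in C3 and 2133 in C4. T-like barcodes carried more Ccl5 in C1, C2 and C3, at 4283, 19898 and 6985 CPM. In C4 they carried less, at 492 CPM against 2133 in myeloid-like barcodes. Macrophage-like cluster 13, most of that class in C2, carried the T cell genes Cd8b1 at 87.1 CPM and Gzmk at 44.4. In macrophage-like barcodes of C2, a Cd8b1 UMI was found in 8.50% and a Gzmk UMI in 9.15%. The Ccl5 level in C2 can therefore include T cell transcripts. Il17a in cluster 13, at 88.5 CPM, rests on very few barcodes, since only 0.218% of macrophage-like barcodes of C2 held a UMI of it. Over the alternatives Ccl5 ran from 112 to 399 CPM in C1 and was as low as 663 CPM in C2; it was 5754 CPM in C3 with a class per barcode and 4138 CPM in C4 with each library clustered alone. Spp1, which encodes osteopontin, was at 45.5 CPM in C1, 11.4 in C2 and 4.24 in C4, with 0 UMIs in C3. With each library clustered alone C4 had 5.57 CPM of Il1b, 13.9 CPM of Ccl3 and 0 UMIs of Spp1. With a class per barcode C3 had 15.5 CPM of Il1b, 7.11 CPM of Ccl3, 76.5 CPM of Ccl4 and 6007 CPM for the list, and C4 had 86.3 CPM of Il1b and 60.4 CPM of Ccl4. That choice counts Ly6c2, which T-like cluster 0 carries, as a myeloid marker. Its values in C3 and C4, Ccl5 among them, can therefore include T cells.

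The list of B cell survival and lymphoid organisation, 11 genes, summed over all immune barcodes to 437 CPM in C1 (429 to 444), 536 in C2 (528 to 544), 878 in C3 (872 to 885) and 1085 in C4 (1074 to 1096). Ltb, which encodes lymphotoxin beta, was at 281 CPM in C1, 442 in C2, 783 in C3 and 859 in C4. Tnfsf13b, which encodes the B cell survival factor BAFF, was at 92.8 CPM in C1 (89.5 to 96.1), 42.0 in C2 (39.7 to 44.4), 2.77 in C3 (2.41 to 3.18) and 0.551 in C4 (0.332 to 0.860). The receptor gene Tnfrsf13b was at 33.4 CPM in C1, 16 in C2, 25.3 in C3 and 69 in C4. Tnfrsf13c, which encodes the BAFF receptor, was at 4.43 CPM in C1, 2.99 in C2, 24.7 in C3 and 94.3 in C4. Tnfrsf17 was at 7.66 CPM in C1, 3.58 in C2 and 2.92 in C3, with 0 UMIs in C4. These sums are over all immune classes, whose shares differ between the libraries.

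The early response genes, 10 genes that answer dissociation and stress within minutes, summed over all immune barcodes to 21656 CPM in C1 (21606 to 21706), 5055 in C2 (5029 to 5081), 1831 in C3 (1822 to 1841) and 2512 in C4 (2496 to 2529). Within T-like barcodes they summed to 9513 CPM in C1 (9409 to 9619), 3272 in C2 (3246 to 3298), 1822 in C3 (1811 to 1832) and 2616 in C4 (2596 to 2636). Within NK-like barcodes, of which C3 had 18 and C4 33, the sum was 9703 CPM in C1 (9643 to 9763), 4780 in C2 (4704 to 4856), 2459 in C3 (2172 to 2773) and 4733 in C4 (4442 to 5037). Within macrophage-like barcodes it was 33436 CPM in C1 (33349 to 33524) and 11727 in C2 (11626 to 11828). Within B-like barcodes it was 8531 CPM in C1 (8230 to 8840), 1716 in C3 (1684 to 1749) and 2120 in C4 (2089 to 2151). In T-like barcodes Fos was at 1599 CPM in C1, 439 in C2, 195 in C3 and 224 in C4. Jun was at 969 CPM in C1, 409 in C2, 246 in C3 and 518 in C4. Junb was at 5370 CPM in C1, 1773 in C2, 931 in C3 and 1416 in C4. Hsp90aa1 was at 349 CPM in C1, 318 in C2, 308 in C3 and 262 in C4. The heat shock gene Hspa1a was at 142 CPM in C1 (129 to 155), 18.8 in C2 (16.9 to 20.9), 0.632 in C3 (0.454 to 0.858) and 0.362 in C4 (0.165 to 0.686) in T-like barcodes. Atf3 in macrophage-like barcodes was at 6168 CPM in C1 and 2059 in C2, and Hspa1b in NK-like barcodes at 207 CPM in C1 and 8.53 in C2. Fosb in NK-like barcodes was at 569 CPM in C1 (554 to 583), 200 in C2 (184 to 216), 111 in C3 (57.3 to 194) and 359 in C4 (283 to 450). In C4 it ran from 205 to 221 CPM under 7 of the 10 alternatives, and with a class per barcode it was 56.7 CPM in C3, and Hspa1b 13.3 CPM in C2. Hspa1a in T-like barcodes of C1 was 232 CPM with a minimum of 1000 UMIs.

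**Figure D4:**
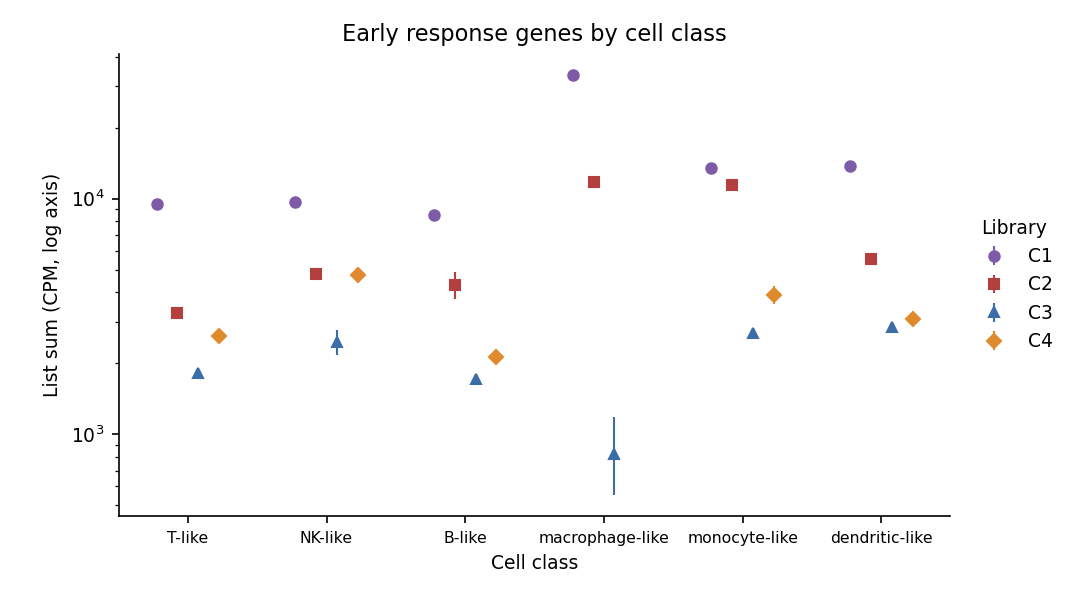
Sum of the early response list (y axis, CPM on a log axis) by cell class (x axis) for the libraries C1 to C4; points are library sums over classes of at least 10 barcodes and bars 95% Poisson intervals. In T-like barcodes C1 lies at 9513 CPM and C3 at 1822 CPM.

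Usage of the beta chain V genes of the T cell receptor was read from UMIs of 35 Trbv genes in T-like barcodes. The leading gene was Trbv13-3 in C1 with 10.1% (9.26 to 11.0%) of Trbv UMIs, Trbv3 in C2 with 12.1% (11.7 to 12.4%) and in C3 with 9.68% (9.48 to 9.89%), and Trbv1 in C4 with 10.8% (10.5 to 11.1%). In C1, Trbv1 held 9.55% (8.71 to 10.4%), an interval that overlaps that of Trbv13-3, so the leading gene of C1 is not settled. Trbv15 held 10.3% (9.95 to 10.6%) in C2 and 4.93% (4.32 to 5.60%) in C1, 5.82% (5.66 to 5.99%) in C3 and 6.03% (5.80 to 6.27%) in C4. Within cluster 11 of C2, Trbv15 held 20.0% (19.1 to 21.0%) of Trbv UMIs over 456 barcodes, a value singled out after it was seen, along with Trbv15 itself. These shares count UMIs, not cells or clones, and a barcode with many receptor UMIs weighs more. Trbv3 lies at chromosome 6, 41048394 to 41048824.

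Transcripts of salivary secretory cells, a fixed list of 20 genes such as Pip, Prol1 and Dcpp3, made up 15428 CPM in C1 (15388 to 15468), 11675 in C2 (11638 to 11713), 9.0 in C3 (8.33 to 9.71) and 14.8 in C4 (13.5 to 16.1) of the kept barcodes. The low sums in C3 and C4 do not rest on the 3 genes named here. Prol1 and Dcpp3 were at 0 CPM in both, and Pip at 0 in C3 and 0.0289 in C4. In C3 the largest members were Epcam at 4.84 CPM, Klk1 at 2.72 and Egf at 1.10. In C4 Klk1 was the largest member, above Epcam at 3.56 CPM and Egf at 1.39. With the longer list, chosen after values were seen, the order of C1 and C2 turned, at 34212 CPM in C1 and 40197 in C2. In near-empty barcodes below 50 UMIs the list made up 30164 CPM in C1 (29745 to 30587), 27974 in C2 (27531 to 28423), 14.5 in C3 (10.4 to 19.6) and 24.5 in C4 (18.2 to 32.3). With the longer list that order turned too, at 113370 CPM in C1 and 144647 in C2. In barcodes of at least 50 and under 200 UMIs the fixed list made up 65477 CPM in C1, 42619 in C2, 42.0 in C3 and 0 in C4; C3 and C4 changed order there, with Poisson intervals of 22.4 to 71.9 CPM and 0 to 43.0 CPM that overlap. In T-like barcodes the fixed list made up 1390 CPM in C1 (1351 to 1431), 1641 in C2 (1623 to 1659), 5.18 in C3 (4.64 to 5.77) and 5.62 in C4 (4.73 to 6.64). In NK-like barcodes it made up 1153 CPM in C1 (1132 to 1174) and 1534 in C2 (1491 to 1578). In macrophage-like barcodes it made up 1260 CPM in C1 (1243 to 1277) and 1421 in C2 (1386 to 1457). In each of these classes C1 lay below C2, the other order from the kept barcodes. T-, NK- and macrophage-like barcodes held 4623, 11937 and 21002 of 571919 list UMIs in C1. In C2 they held 31210, 4855 and 6303 of 368025. Most list UMIs of the kept barcodes therefore lay outside these classes. Mucl2, a secretory gene outside the list, at chromosome 15, 103895855 to 103899312, made up 13026 CPM in C1 (12989 to 13063), 18775 in C2 (18727 to 18823) and 0.0868 in C4 (0.0179 to 0.254) of the kept barcodes, with 0 UMIs in C3. No library's tissue was read from these levels.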

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

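Of the tests in this part, the level of Gzmm within C3 and the direction of early response genes across cell classes, with its minimum of 40 barcodes and its count over every pair, were chosen only after the result was seen.

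Transcripts of the salivary list appeared in barcodes below 50 UMIs, which lie outside the cell classes, above the limit that a count of 0 allows. They were at 30164 CPM in C1, 27974 in C2, 14.5 in C3 and 24.5 in C4. In C3 most of this was Klk1, at 6.36 CPM, and Epcam, at 3.53. In C4 the largest members were Klk1 at 6.86, Bpifa2 at 5.39 and Epcam at 4.41. Of T-like barcodes, 99.2% in C1 and 98.6% in C2 held at least 1 UMI of the list. Free RNA should give abundant members the ratio they have in barcodes of at least 50 and under 200 UMIs, within 2-fold, but Klk1 in macrophage-like barcodes of C1 was at 2.00 times that ratio (1.90 to 2.11), Klk1 in macrophage-like barcodes of C2 at 1.80 times (1.58 to 2.04) and Dcpp3 in NK-like barcodes of C2 at 0.540 times (0.415 to 0.691). Read by the point value alone, as first done, the bound was met; read by the whole interval, a reading adopted after that result was seen, free RNA is left undecided. Doublets with epithelial cells should put over 50% of list UMIs into the 5% of T-like barcodes with the most, and under 25% would argue against them. Those barcodes held 15.1% in C1 and 27.3% in C2, which leaves a contribution of doublets open. Doublets as the only source in T-like barcodes are argued against, since nearly all of these held a list UMI. Their median was 7 list UMIs in C1 and 6 in C2. Free RNA, doublets or both may contribute, and no biological explanation was tested.

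Cluster 0, led by Gzmm and Ly6c2, held 4467 T-like barcodes of C3. One expanded T cell clone is argued against, since the leading gene Trbv16 held 10.5% (10.2 to 10.8%) of the cluster's Trbv UMIs in C3, where a clone would put over 50% in 1 gene. A shift of the whole library C3 stays open. Gzmm in its other T-like clusters over cluster 0 was 0.20, at the bound of 0.2 set for an argument against a shift. It was at 287 CPM in cluster 0, 57.5 CPM in the other clusters and 19.9 CPM in B-like barcodes. Gzmm leads cluster 0 by its fold over the other barcodes of these same data. A low ratio was therefore favoured in advance, and the test cannot decide. In C4, Gzmm was at 107 CPM in cluster 0 and 3.0 CPM in other T-like barcodes. The genotype and tissue of C3 are not known here, so no biological explanation was tested.

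Early response genes differed between libraries. A mix of the named classes as the only cause is argued against, since within T-like barcodes the highest library was 5.22 times the lowest. The T-like class held different clusters in each library, so a mix of T-like subsets stays open. The mix of classes can still add to the sums over all immune barcodes, at 21656 CPM in C1 and 1831 in C3. Macrophage-like barcodes, at 33436 CPM in C1, were 44.5% of C1 and 0.281% of C3. Handling or digestion that acts on every cell type is left undecided: 0 of 11 pairs of libraries with at least 40 barcodes each within B-, NK-, macrophage-, monocyte- or dendritic-like barcodes differed in the direction opposite to T-like barcodes, but these pairs reuse 4 libraries, 8 of the pairs hold C1, and the outcome was known when the test was written. Over every pair, 1 of 30 was opposite, macrophage-like C3 (823 CPM, 551 to 1183, 24 barcodes) and C4 (184 CPM, 4.65 to 1024, 4 barcodes), with intervals that overlap; an earlier form of the test had split libraries by their T-like level. A difference of tissue or genotype that acts on all classes predicts the same directions and stays open, untested. The sizes varied, with C1 over C2 at 2.91 in T-like and 1.19 in monocyte-like barcodes.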

How the results depend on the processing

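No paired analysis was possible because each group has 1 sample and no result comes from a test. The 2 alternatives for SS against control were not run because the libraries are not tied to samples. Removal of the top 5% of doublet scores, the first naming rule, the CPM total without abundant contaminants, near-empty barcodes of at least 50 and under 200 UMIs, the longer salivary list, the list sums without Nr4a1, without shared genes or under each alternative, Igha in B-like barcodes and the further restriction on T-like genes were chosen after seeing the data. Of the 36 alternative values each, 35 B-like, 32 NK-like, 22 T-like and 20 myeloid-like shares stayed within the interval of the main value; the cause of the other shifts was not tested.

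With a minimum of 1000 UMIs the T-like share was 12.2% in C1 and 68.7% in C2, and the NK-like share 28.0% in C1. With at most 5% mitochondrial UMIs the T-like share was 69.9% and the myeloid-like share 10.8% in C2. At resolution 0.5 the myeloid-like share of C1 was 48.7%. At resolution 2 the T-like share of C3 was 86.4%, and the myeloid-like shares were 43.0% in C1, 10.2% in C2 and 1.79% in C3. With each library clustered alone the T-like shares were 61.1% in C2, 71.2% in C3 and 56.4% in C4, the myeloid-like shares 45.0% in C1, 10.0% in C2 and 0.616% in C4. There the NK-like share of C1 was 22.6% and the B-like share of C2 was 0%. With a class per barcode the T-like shares were 12.4%, 67.9%, 67.1% and 63.1% in C1 to C4, the myeloid-like shares 60.1%, 15.2%, 22.8% and 3.18%, and the NK-like shares 14.6% in C2 and 1.11% in C3. Ly6c2, which cluster 0 carries at 2645 CPM, is among the myeloid markers that this choice sums. Nkg7, which T-like barcodes of C2 carry at 4072 CPM, is among its NK markers. Without the top 5% of doublet scores the T-like share of C2 was 56.1%, the myeloid-like shares were 44.5% in C1 and 10.2% in C2, and Trbv3 held 13.2% in C2. Under the first naming rule the T-like shares were 84.4% in C3 and 48.1% in C4, the myeloid-like shares 41.2% in C1 and 10.1% in C2, and Trbv1 held 12.5% in C4; that rule leaves 1 T-like cluster unnamed.

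The salivary list in kept barcodes of at least 1000 UMIs was 15282 CPM in C1 and 11626 in C2, and the longer list in kept barcodes 34212 and 40197. Below 20 UMIs the list was 28536 in C1. In barcodes of at least 50 and under 200 UMIs it was 65477 in C1, 42619 in C2, 42.0 in C3 and 0 in C4, and the longer list below 50 UMIs was 113370 in C1, 144647 in C2 and 35.8 in C4.

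Of the shares of T-like barcodes with a UMI of a gene, 18 of 64 moved by more than 1.5-fold on thinning to 1 depth. Of the single-gene levels, 37 of 367 did with a class per barcode, 24 of 395 with each library clustered alone, 13 of 443 with a minimum of 1000 UMIs, 10 of 443 without the top 5% of doublet scores, 9 of 425 with at most 5% mitochondrial UMIs, 4 of 425 at resolution 2, 4 of 443 with doublet calls kept, 1 of 443 at resolution 0.5, 1 of 425 under the first naming rule and 0 of 443 with the CPM total without abundant contaminants. Of 781 list sums under the alternatives, 13 moved as much. Of 8 list sums without Nr4a1, 1 moved as much, the B cell maturation list in C1. Small classes limit depth; the macrophage-like class of C4 has 4 barcodes.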

Other observations

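Marker lists of cell types that named no cluster were also summed over the kept barcodes of each library. Erythroid genes such as Hbb-bs made up 281 CPM in C1, 0.381 in C2, 1.29 in C3 and 3.62 in C4. Mast cell genes made up 6.18 CPM in C1, 7.17 in C2, 4.72 in C3 and 1.82 in C4. Eosinophil genes made up 7.88 CPM in C1, 16.5 in C2, 1.91 in C3 and 0.145 in C4, and basophil genes 0.486 CPM in C1, 0.222 in C2, 6.82 in C3 and 1.51 in C4. Fibroblast genes made up 11.1 CPM in C1, 14.8 in C2, 0.148 in C3 and 0.116 in C4. Cell cycle genes such as Mki67 made up 104 CPM in C1, 333 in C2, 354 in C3 and 224 in C4.

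The values that follow were singled out after they were seen. Macrophage-like barcodes of C1 and C2 lay mostly in different clusters. Cluster 13, with Cxcl9, a chemokine gene induced by interferon gamma, at 1159 CPM and Ccl8 at 441 CPM, held 4.58% (3.78 to 5.49%) of the class in C1 and 69.7% (65.3 to 73.9%) in C2. Cluster 4, with Cxcl2 at 5069 CPM and the heat shock gene Hspa1a at 1963 CPM, held 77.1% (75.3 to 78.7%) in C1 and 5.88% (3.91 to 8.44%) in C2. Cluster 23, B-like with a mean doublet score of 0.158, carried the T cell gene Cd8b1 at 321 CPM over all its barcodes. Cd8 UMIs without Cd4 were found in 46.4% of its 69 barcodes in C3 and in 1.16% of its 86 barcodes in C4. The unnamed cluster 10, with 561 of its 611 barcodes in C2, had a median depth of 1162 UMIs, and the unnamed cluster 14, led by Smgc and Hbb-bs, had all 427 of its barcodes in C1 at a median of 967 UMIs. The ribosomal RNA overlapping gene Gm42418 was high in barcodes of at least 50 and under 200 UMIs of every library. It made up 334759 CPM in C1, 437142 in C2, 273595 in C3 and 279031 in C4. In kept barcodes it made up 23646 CPM in C1, 26159 in C2, 12348 in C3 and 14730 in C4.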
